A study of Mus musculus with 12 samples.

How the data were processed

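Total RNA from mouse glomeruli and primary podocyte cultures was labelled with Cy3 and hybridised to Agilent one-colour arrays, 1 array per sample, per the labels' protocols. The 12 samples form 6 groups of 2: glomeruli of control and of tamoxifen-treated mice, and cultures at day 4 and day 7, each mock-treated or tamoxifen-treated. The genotype labels number the second floxed gene differently from sample to sample, and the series title, which names Foxc1 and Foxc2, was followed.

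The deposited scanner files hold spot intensity on a linear scale, written by Agilent Feature Extraction 11.5.1.1, per the file headers, which record a background-subtracted processed signal, the median signal, a local background and flags for each spot. The authors' deposited value table holds log2 values. Its scale, centring and direction are not stated, and they were found by setting each column against its array. The columns matched the log2 processed signal shifted to its 75th percentile (r = 1.0) up to a constant, the median difference being 0.094 to 0.12 per column. With that difference taken out, 99.9% to 100.0% of probes lay within 0.1. Genes were not centred, and column medians were -4.14 to -3.82. As values of single samples the columns carry no direction, so none of the 3 stays unknown. There were 0 array columns that belonged to no sample.

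The log2 of the processed signal was taken and each array's 75th percentile subtracted. Control spots and spots marked as outliers (83 to 134 per array) were left out, 0 spots were saturated, and replicate spots of a probe were averaged. The 75th percentile of the signal was 505.2 to 759.9 units per array, the median local background 24.5 to 34.0 units, and 57.9% to 63.4% of spots were well above background. Of 43020 spots with 39429 distinct probes, 26581 probes had 1 gene symbol, 0 had several and 12848 had none. Names came from the RefSeq accession on the array, matched without versions to a table of assembly GRCm38.p6, which matched 26581 of 28115 such probes. The arrays' own design build differs, so no coordinates are given. Probes well above background on at least 2 of the 12 arrays were kept, 26421 in all, of which 19998 had a symbol. Where a gene had more than 1 probe (3986 genes), the probe with the highest mean over the 12 arrays was used, which left 15217 genes. Among called genes with more than 1 probe, another probe pointed the other way for 4 of 89 in glomeruli (Dcaf12l2, Gbp6, Ldb3 and Tspyl5), 0 of 4 at day 4 and 0 of 23 at day 7.

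Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 fit of the 6 group means over all 12 arrays, with 6 residual and 1.87 prior degrees of freedom and no block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and SE is limma's. The contrasts were tamoxifen against its control in glomeruli, at day 4 and at day 7, the difference between the 2 culture responses, the difference between the glomerular and the mean culture response, mock day 7 against mock day 4, and mock cultures against control glomeruli. For a probe not well above background on any array of a group the size can at most be bounded. Such a bound holds for this background subtraction and not for normexp. Data were simulated with each gene's limma spread as independent noise, alike on all 12 arrays. In glomeruli the fit found 48%, 86%, 90% and 100% of 50 genes changed by log2 sizes of 1, 2, 3 and 4, with 14 false calls. It found 54%, 76%, 92% and 98% at day 4 with 7 false calls, and 54%, 84%, 90% and 100% at day 7 with 10. The simulation held no pairing of samples, no correlation between genes and no wider spread near background. These shares may therefore overstate the power on the real arrays. The number of arrays limits the precision.

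The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The rule named the 2 target genes. For each tamoxifen comparison it took the 8 largest rises and the 8 largest falls among called genes with both treated arrays on one side of both controls and at least 1 array of each group well above background, leaving out symbols that only number a transcript or clone. It took 5 each way for the other contrasts, up to 3 each way among called genes dim throughout one group by their bound, up to 4 called members of each list, and up to 2 members as values where none was called. Where fewer than 8 genes were called, all were named and filled to 8 each way by unadjusted p. The 24 lists covered podocyte genes (slit diaphragm and foot process, transcription factors, surface and secreted), basement membrane, actin and focal adhesion, markers of endothelial, mesangial, tubule, parietal, immune and red blood cells, and injury and matrix, cell cycle, p53, interferon, cytokine, Notch, Wnt, cholesterol synthesis, estrogen, unfolded protein, immediate early, hypoxia and oxidative phosphorylation genes. For 6 listed genes (Cd68, Ly6c2, Hbb-b1, Mx1, Mx2 and Hspa1b) no named probe was found. Foxl1 belonged to the podocyte transcription factor list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists, with an estimated correlation and fry as alternatives.

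Slide positions in the file headers put the glomeruli, the day 4 cultures and the day 7 cultures on 3 slides of 4 arrays, so each tamoxifen comparison lies within 1 slide, and the fit on a comparison's own 4 arrays is its within-slide value. The labels number samples 1 and 2 in each group. Over genes, the deviations of same-numbered culture samples from their group means correlated at 0.40 to 0.55 (0.51 at day 4 and 0.54 at day 7). The culture numbers were therefore read as pairing the samples, a reading taken from the data and not from the labels. On each culture slide replicate 1 lay at positions 1 and 2 and replicate 2 at positions 3 and 4. A shared source and slide position thus cannot be told apart as the origin of this correlation. The counts given first come from the fit without a block, which was fixed before the data were examined, and values with a replicate block stand beside the culture results. In glomeruli that correlation was 0.21. There the controls lay at positions 1 and 2 and the treated samples at positions 3 and 4, so treatment and position cannot be told apart.

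Alternatives were normexp background correction (offset 50, on the median signal, since no mean signal was read here), quantile normalization, scaling to the median, no filter on dim probes, a filter asking for all 4 arrays of a comparison, the mean of a gene's probes, eBayes with trend and robust options, own-array fits, separate fits for glomeruli and cultures, a replicate block, the authors' value table, a 2-fold minimum, and leaving out each array in turn. A block shared by all culture groups was added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Probes without a symbol were tested and counted but not described. A few genes that the rule would name are not reported here.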

Results

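Gene expression was measured on 12 arrays in mice that carry floxed Foxc1 and Foxc2 and a Cre recombinase that tamoxifen switches on. Foxc1 and Foxc2 are forkhead transcription factors. The samples fell into 6 groups of 2. Glomeruli, the filtering units of the kidney, came from control mice and from mice injected with tamoxifen on 3 days at 8 weeks of age, with isolation on day 7. Podocytes, the epithelial cells that wrap the glomerular capillaries, were grown as primary cultures and kept for 4 or 7 days as mock cultures or with tamoxifen. The series was set up to ask what adult podocytes lose without the 2 factors. Every treated sample had the drug along with whatever recombination it caused, so these comparisons measure both together. The glomerular labels name separate mice, while the culture labels do not say whether the numbered samples were separate cultures. The spread between culture samples may therefore be technical. Every p-value from the fit on all 12 arrays draws on it, those of glomeruli included, since each gene has a pooled spread. Each array had between 57.9% and 63.4% of its spots well above background and 0 saturated spots, and replicate arrays correlated at 0.983 to 0.99 across genes. After filtering, 15217 named genes were tested, and the first principal component, which separated glomeruli from cultures, held 84.5% of the variance. The number of arrays limits the precision: 2 against 2 samples cannot give a two-sided exact permutation p under 0.333, so all adjusted p-values are limma's, from a fit across all genes that shares the spread of all 12 arrays.

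Foxc2 fell in all 3 comparisons. In control glomeruli its probe read 2.10 and 2.24 on the log2 scale relative to the array's 75th percentile, and in treated glomeruli -1.12 and -0.19, so that it fell by 2.82 (SE 0.51, n = 2 against 2, adjusted p = 0.037 by limma). In cultures the mock values were 1.76 and 1.45 at day 4 and 1.38 and 1.42 at day 7. No treated culture read well above background, with values of -7.11 and -5.42 at day 4 and -7.80 and -7.37 at day 7, so on this scale Foxc2 was at least 139-fold lower at day 4 (adjusted p = 0.0019) and at least 151-fold lower at day 7 (adjusted p = 0.00071). Such a bound sets the mean of the bright group against, on each array of the dim group, the higher of the probe's own value and the lowest signal among probes well above background. The size depends on the background model: with normexp, which adds an offset to every signal, Foxc2 was at -3.20 at day 4 (adjusted p = 0.022) and -4.57 at day 7 (0.0038). Foxc1 was lower in every treated sample than in every control of its comparison without passing the threshold. It read 2.92 and 2.80 in control and 0.92 and 1.09 in treated glomeruli (difference -1.86, SE 1.69, adjusted p = 0.63). That SE comes from the spread pooled over all arrays, to which the widely differing treated cultures contribute. On the glomerular arrays alone limma's adjusted p was 0.26. Foxc1 read 3.09 and 4.21 in mock and -5.78 and -1.74 in treated cultures at day 4 (difference -7.41, adjusted p = 0.14). At day 7 it read 2.62 and 4.33 in mock and -8.20 and -3.26 in treated cultures (difference -9.21, adjusted p = 0.057). In cultures treated replicate 1 did not read well above background on either day, so these 2 sizes are not settled. Without 1 treated array they were -5.39 or -9.43 at day 4 and -6.74 or -11.68 at day 7. With normexp Foxc1 was at -4.94 at day 4 (adjusted p = 0.022) and -6.50 at day 7 (adjusted p = 0.005), so that it passed on both days. At day 7 it also passed with median scaling (adjusted p = 0.047) and with eBayes' trend and robust options (0.04). With the replicate number as a block Foxc1 passed at day 7 (adjusted p = 0.032), and with 1 block shared by all cultures, an alternative chosen after the data were seen, it passed at day 4 (adjusted p = 0.016) and day 7 (adjusted p = 0.0063). The glomerular call of Foxc2 was lost without control replicate 1 (adjusted p = 0.11), control replicate 2 (0.084), treated replicate 1 (0.18), either day 4 mock array (0.068) or any day 7 array (0.064). That call was also lost with normexp (adjusted p = 0.066), without a filter on dim probes (0.051), with the replicate block (0.061) and on the glomerular arrays alone (0.26). Each gene has 1 probe, and whether it lies in the deleted part of the gene is unknown, so these readings check the labels only as far as the probe reports the deletion.

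**Figure D1:**
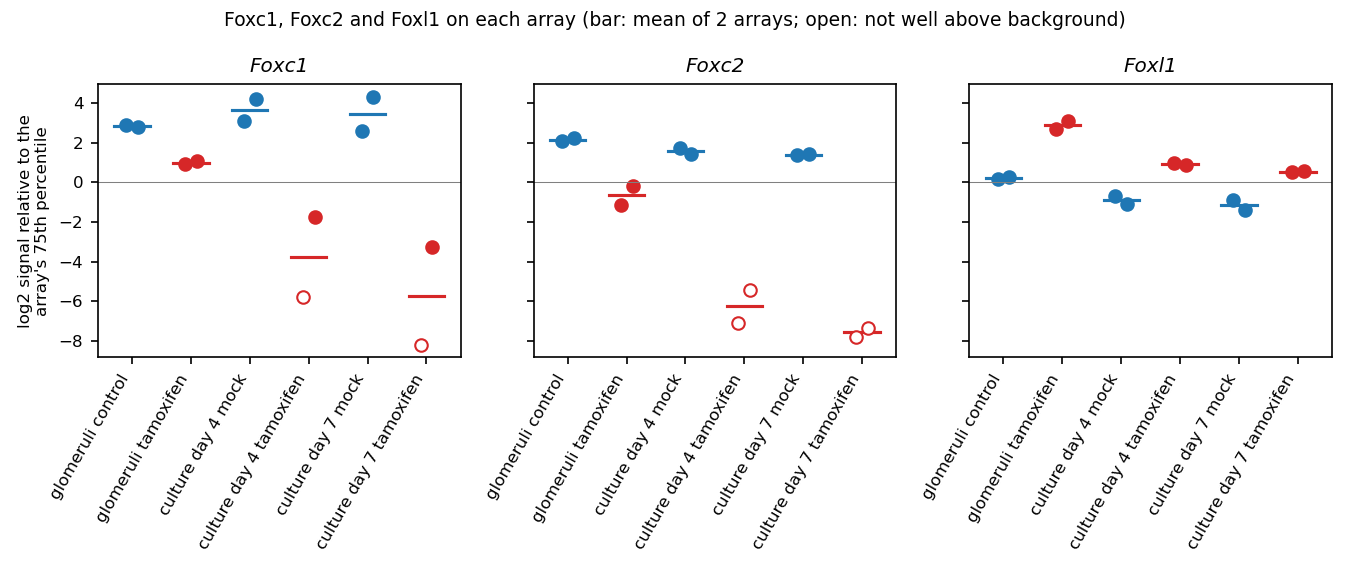
Log2 signal relative to the array's 75th percentile (vertical axis) of Foxc1, Foxc2 and Foxl1 on each of the 12 arrays by group (horizontal axis), with bars at the mean of 2 arrays and open points for arrays not well above background. Foxc2 lies at 1.38 to 1.76 in the 4 mock cultures and at -5.42 or below in the 4 treated cultures, while Foxl1 lies higher in every treated sample than in its controls.

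In glomeruli 402 genes changed with tamoxifen, 268 of them upwards and 134 downwards, and 261 by at least 2-fold. The largest rises among genes measured in both groups were those of Angptl7, a secreted angiopoietin-like protein (4.32 on the log2 scale, SE 0.69), Adamts8, a secreted metalloproteinase (3.49, SE 0.36), the carboxylesterase Ces1f (2.74, SE 0.52) and Foxl1, the forkhead gene next to Foxc2 (2.70, SE 0.21). Hsd3b2 (2.62), Sectm1b (2.47), Creg2 (2.40) and the forkhead factor Foxe1 (2.38) followed, with limma adjusted p-values of 0.0061 to 0.045 over these 8 genes. The largest falls were in haemoglobin genes: Hbb-bt fell by 5.82 (SE 1.01), Hbb-b2 fell by 5.50 (SE 0.60) and Hba-a2 fell by 4.50 (SE 0.89). Hbb-bt and Hbb-b2 are similar beta-globin genes, and Hba-a2 is an alpha-globin gene with a near-identical copy of its own. The probes may not separate the copies within either kind. Wfdc21 fell by 3.26, Foxc2 by the amount given above, the connexin gene Gja3 fell by 2.40, the interferon-induced Ifitm1 fell by 2.06 and Ms4a1, which encodes the B cell antigen CD20, fell by 1.94. The adjusted p-values of these 8 falls were 0.013 to 0.047. Among genes dim in one group, Nrcam was at least 5.46-fold, Nmur2 at least 3.81-fold and Fmo4 at least 3.22-fold higher (adjusted p = 0.028, 0.013 and 0.041). Alas2, the enzyme of haem synthesis in red cell precursors, was at least 9.11-fold lower, Kcnj14 at least 5.99-fold and Iqcf5 at least 3.31-fold lower (adjusted p = 0.023, 3.2e-05 and 0.00013). In all of these genes both treated arrays lay on the same side of both controls. Of the 30 calls named for glomeruli, those of Adamts8, Creg2, Foxe1, Foxl1, Hbb-b2, Iqcf5, Kcnj14, Nmur2 and Slc22a6, 9 in all, passed in each of the 12 fits that left out 1 array, and each other call was lost in at least 1. The total was 89 without treated replicate 1 and 114 without control replicate 1. It was 128 without either day 4 mock array, 97 without either day 4 treated array, 188 without either day 7 mock array and 140 without either day 7 treated array, which enter through the shared spread. Of the named calls, those of Ces1f, Sectm1b, Hba-a2, Synpo and Sdhb were each lost in 11 of the 12 fits that left out 1 array. In the fit on all 12 arrays 2781 genes had an unadjusted p under 0.05. Fitted on the 4 glomerular arrays alone, limma called 0 genes, and with normexp on all arrays it called 5. With each array scaled to its median the calls split into 281 higher and 80 lower.

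Of 3 podocyte lists 2 were lower in treated glomeruli, those of the slit diaphragm and of the surface. On the same arrays tubule genes were higher, with a median of 1.21, and endothelial genes had a median of -0.33 without passing (adjusted p = 0.055). Of 26 slit diaphragm and foot process genes 14 were lower on both treated arrays, with a list median of -0.33 (limma's camera, preset correlation, adjusted p = 0.003; adjusted p = 0.62 with an estimated correlation), and 1 passed alone. Synpo, an actin-associated protein of foot processes, fell by 1.32 (SE 0.24, adjusted p = 0.037). That call was lost in 11 of the 12 fits that left out 1 array. Adjusted over the list alone, 5 fell and 0 rose. Of 31 podocyte surface and secreted genes, with a median of -0.35 (adjusted p = 0.003; adjusted p = 0.62 with an estimated correlation), only Thsd7a, a podocyte membrane protein, passed; it fell by 1.00 (SE 0.13, adjusted p = 0.017), and 2 fell adjusted over the list alone. Both list calls were lost without control replicate 2 (adjusted p = 0.053 and 0.51). Of 15 podocyte transcription factors Foxl1 rose and 0 fell, 2 rose adjusted over the list alone, and the list did not pass (median -0.22, adjusted p = 0.68). Of 16 basement membrane genes 0 passed, 1 fell adjusted over the list alone, and the list did not pass. Its median was 0.01 where the mean was -0.04 and the test pointed down (adjusted p = 0.62). Lama1 was at 0.96 and Hspg2 at -0.78.

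Markers of other cell types moved in both directions. Tubule genes were higher: 22 of 24 had a higher mean and 19 were higher on both treated arrays, with a median of 1.21 (camera, adjusted p = 1.9e-10; adjusted p = 0.087 with an estimated correlation). Slc22a6, the organic anion transporter of the proximal tubule, rose by 1.65 (SE 0.19, adjusted p = 0.015). Slc12a1, the salt transporter of the thick ascending limb, rose by 1.48 (SE 0.25, adjusted p = 0.031). Adjusted over the list alone, 12 rose. Red blood cell genes were lower, with a median of -4.50 over 5 members (adjusted p = 4.6e-05; adjusted p = 0.60 with an estimated correlation). Of these Hbb-b2, Hba-a2 and Alas2 fell, 3 in all, and 4 fell adjusted over the list alone. Immune cell genes were lower, 18 of 20 by their means, with a median of -0.73 (adjusted p = 0.0062, lost at 0.083 without control replicate 1; adjusted p = 0.67 with an estimated correlation). Of these 0 passed, 2 fell adjusted over the list alone, and Tyrobp was at -1.41 and Lyz2 at -1.37. Of 22 endothelial genes 20 were lower by their means and 0 passed (median -0.33, adjusted p = 0.055), with Cldn5 at -0.78 and Emcn at -0.61. Of 17 mesangial and mural genes 16 were higher by their means and 0 passed (median 0.33, adjusted p = 0.055), with Ren1, which encodes renin, at 1.41 and Myh11 at 1.33. With the replicate block the endothelial and mesangial lists passed (camera, adjusted p = 0.027 and 0.037). Of 11 parietal epithelial genes 0 passed (median 0.03, adjusted p = 0.33), with Krt8 at 1.48. In the endothelial, mesangial and parietal lists 0 passed adjusted over the list alone.

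Mitochondrial and interferon genes were higher in treated glomeruli. Of 24 oxidative phosphorylation genes 21 were higher on both treated arrays, with a median of 0.37 (camera, adjusted p = 1.9e-10; adjusted p = 0.60 with an estimated correlation). Sdhb, a subunit of respiratory complex II, rose by 0.53 (SE 0.11, adjusted p = 0.048), and 12 rose adjusted over the list alone. These are the arrays on which tubule genes had a median of 1.21. Of 19 interferon response genes 18 were higher by their means, with a median of 0.55 (adjusted p = 7.8e-05, lost at 0.068 without control replicate 2; adjusted p = 0.62 with an estimated correlation). Over all genes 0 passed, adjusted over the list alone 2 rose, and Isg15 was at 2.10 (adjusted p = 0.07). Cell cycle genes had a median of 0.25 over 26 members (adjusted p = 0.019; adjusted p = 0.81 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose by 2.01 (SE 0.24, adjusted p = 0.015), also the 1 call adjusted over the list alone. Of 19 genes of the unfolded protein response 0 passed by either adjustment, and their median was -0.30 (adjusted p = 0.023; adjusted p = 0.62 with an estimated correlation), with Calr at -0.76. Those last calls were lost without control replicate 2 (adjusted p = 0.89 for the cell cycle and 0.26 for the unfolded protein response) and without treated replicate 2 (0.1 and 0.19). The cell cycle call was also lost without a filter on dim probes (adjusted p = 0.055) and with the mean of a gene's probes (0.053). The remaining lists did not pass. Actin and focal adhesion genes had a median of -0.05 with a mean of 0.10 and a test pointing up (adjusted p = 0.9), 2 rose adjusted over the list alone, and Acta2, smooth muscle actin, rose by 1.1 (SE 0.14, adjusted p = 0.016). The p53 response list had a median of -0.07 (adjusted p = 0.62), 2 rose and 1 fell adjusted over the list alone, and its member Trp53inp1 fell by 1.11 (SE 0.15, adjusted p = 0.022). The medians were 0.08 for injury, fibrosis and matrix (adjusted p = 0.5), 0.14 for cytokines, with a mean of -0.22 and a test pointing down (0.86), and -0.17 for Notch (0.61). They were -0.04 for Wnt, with a mean of 0.07 and a test pointing up (0.61), 0.23 for cholesterol synthesis (0.095), -0.18 for estrogen response (0.45), 0.24 for immediate early genes (0.21) and 0.22 for hypoxia and glycolysis (0.095). In these 8 lists 0 members passed over all genes, and adjusted over the list alone 1 Wnt gene rose. Their largest differences included Postn at 2.11, Col1a1 at 1.82, Ccl5 at -1.48, Wnt4 at -2.13 and Car9 at 1.60. Limma's fry, which asks whether a list's genes move one way on balance, called only the tubule (adjusted p = 0.0052), red blood cell (0.023) and oxidative phosphorylation lists (0.039).

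**Figure D2:**
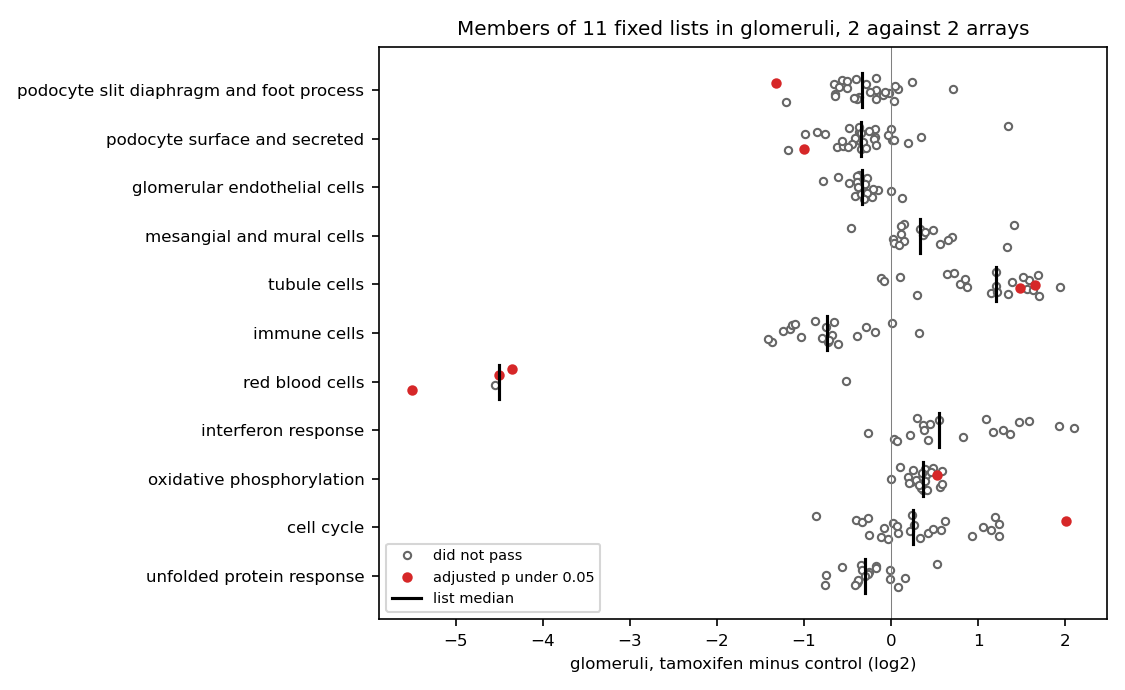
Log2 change in glomeruli, tamoxifen minus control with 2 against 2 arrays (horizontal axis), of each member of 11 lists fixed before the data were examined (vertical axis), with filled points for genes at an adjusted p under 0.05 and lines at list medians. Tubule genes centre on 1.21 and red blood cell genes on -4.50, while the slit diaphragm and surface lists of podocytes centre on -0.33 and -0.35.

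In cultures at day 4, 32 genes changed, 14 upwards and 18 downwards, and 28 by at least 2-fold. The largest falls included those of Itih2, whose product is a hyaluronan-binding inhibitor chain and which fell by 3.56 (SE 0.34). Ptgis, prostacyclin synthase, fell by 1.94 (SE 0.24). Sprr1a fell by 3.24, Sh2d4a fell by 3.03, Clec2d fell by 2.95, Shisa3 fell by 2.72 and Hspa12a, of the heat shock protein family, fell by 2.03, with limma adjusted p-values of 0.0071 to 0.049 over these genes. Only 7 genes measured in both groups met the rule for named rises: Pitpnm3 (2.69, SE 0.31), Foxl1 (1.81, adjusted p = 0.026), the complexin Cplx3 (1.72, SE 0.18), Nhsl2 (1.62, SE 0.21), Wnt9a, a secreted Wnt ligand (1.49, SE 0.13), Klhl29 (1.20, SE 0.17) and Klhl21 (0.88, SE 0.10), at adjusted p-values of 0.0058 to 0.049. The cytokine Lif was at least 5.02-fold higher (adjusted p = 0.013), Ptprt at least 3.89-fold (adjusted p = 0.0027) and Adipoq, which encodes adiponectin, at least 3.86-fold higher (adjusted p = 0.043). Adamts18, another metalloproteinase, was at least 5.42-fold and Ctxn3 at least 1.73-fold lower (adjusted p = 0.00071 each). In all of these genes both treated arrays lay on the same side of both mock arrays. Of the 22 calls named for day 4, those of Foxc2, Ptprt, Adamts18 and Ctxn3, 4 in all, passed in each of the 12 fits that left out 1 array. With the replicate number as a block, 90 genes passed (46 up, 44 down), but Klhl29 (adjusted p = 0.066), Sprr1a (0.064), Clec2d (0.055), Shisa3 (0.054), Hspa12a (0.073) and Inf2 (0.059) did not. The total was 7 and 11 without day 4 treated replicates 1 and 2, 13 without day 4 mock replicate 2, 19 without either treated array of the glomeruli or of day 7, and 79 without either day 7 mock array. Foxl1 was lost without day 4 mock replicate 2 (adjusted p = 0.18), day 4 treated replicates 1 (0.15) and 2 (0.14) or either day 7 treated array (0.061). In the fit on all 12 arrays 1668 genes had an unadjusted p under 0.05, and on the 4 day 4 arrays alone limma called 0 genes. With median scaling the calls split into 26 higher and 17 lower, and under normexp the median of all genes was 0.19 in place of 0.02, with 4740 genes called higher and 313 lower. Under normexp Adamts18 was at 0.34, Ctxn3 at 1.02, Shisa3 at 0.14 and Hspa12a at 0.48, so these 4 falls did not hold. Shisa3 lay below that median of all genes, so its sign there may count a shift of all genes.

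At day 4 the list test called 4 lists, and 0 of them with an estimated correlation. Hypoxia and glycolysis genes were higher, 17 of 18 by their means, with a median of 0.43 (camera, adjusted p = 0.0097; adjusted p = 0.82 with an estimated correlation), and 0 passed alone. The glycolytic enzyme gene Pgk1 was at 1.02 and Pdk1 at 1.00. Interferon genes were lower, 17 of 19 by their means, with a median of -0.37 (adjusted p = 0.0097; adjusted p = 0.82 with an estimated correlation), and 0 passed alone, with Ifit3 at -1.62. Both calls were lost without day 4 mock replicate 2 (adjusted p = 0.42 and 0.09) and without day 4 treated replicate 1 (0.35 and 0.1), which left 2 lists called in each case. Both were also lost with normexp (adjusted p = 1 for hypoxia and 0.48 for interferon genes). Actin and focal adhesion genes were higher, 20 of 25 by their means, with a median of 0.18 (adjusted p = 0.0097; adjusted p = 0.82 with an estimated correlation), and 0 passed over all genes but 1 rose adjusted over the list alone. Under normexp that test pointed down (adjusted p = 0.13), and with quantile normalization it did not pass (0.077). The smooth muscle actin gene Actg2 was at 1.51 (adjusted p = 0.065). Immediate early genes were lower, 12 of 16 by their means, with a median of -0.36 (adjusted p = 0.042; adjusted p = 0.82 with an estimated correlation), with Dusp1 at -1.56 and Klf2 at -1.32. That call was lost with the replicate block (adjusted p = 0.11), without day 4 mock replicate 2 (0.12), day 4 treated replicate 2 (0.39) or either day 7 treated array (0.06). It was lost as well with normexp (adjusted p = 0.17), with quantile normalization (0.077) and on the 4 day 4 arrays alone (0.05). Limma's fry for movement one way called 0 lists at day 4. Its mixed form, which counts changes both ways, passed for several, among them basement membrane genes (adjusted p = 7.2e-05). The block brought in the immune list downwards (0.029) and the unfolded protein response upwards (0.030).

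Podocyte genes did not pass as groups moving one way at day 4. Fry's mixed form gave adjusted p = 9.4e-06 for slit diaphragm genes, 0.0015 for transcription factors and 0.0043 for surface and secreted genes. It asks only whether some members change, in either direction. Of 26 slit diaphragm genes the formin Inf2 fell by 0.82 (SE 0.11, adjusted p = 0.043), 5 fell and 1 rose adjusted over the list alone, and the median was -0.03 (adjusted p = 0.083). Podocyte transcription factors had a median of -0.26 (adjusted p = 0.28) with Foxl1 up, and 1 rose and 1 fell adjusted over the list alone. Surface and secreted genes had a median of -0.04, a mean of 0.03 and a test pointing down (adjusted p = 0.49), with 0 passing over all genes and 1 rise and 2 falls adjusted over the list alone. Sema3e was at -1.97 and Enpep at 1.73, which passed with the replicate block (adjusted p = 0.046). The other lists did not pass. Their medians were 0.08 for basement membrane (adjusted p = 0.66), 0.03 for endothelial genes, with a mean of -0.03 and a test pointing down (0.54), -0.40 for mesangial (0.29), 0.28 for tubule (0.18), 0.39 for parietal (0.31), -0.47 for immune (0.28) and 0.21 for red blood cell genes (0.31). They were 0.31 for injury and matrix (0.28), 0.19 for cell cycle (0.28), 0.07 for p53 (0.75), 0.03 for cytokines (0.54), 0.04 for Notch (0.28), 0.19 for Wnt (0.28) and -0.13 for cholesterol synthesis (0.28). For estrogen response the median was 0.01, with a mean of -0.16 and a test pointing down (0.54), for the unfolded protein response it was 0.21 (0.083) and for oxidative phosphorylation 0.13 (0.052). Of their members Lif alone passed over all genes. Adjusted over the list alone, 2 mesangial genes fell, 2 parietal genes rose and 1 fell, 1 injury gene rose, 2 cytokines rose and 1 fell, and 1 Wnt gene rose and 1 fell. Rgs5, a pericyte signalling regulator, was at -1.88 (adjusted p = 0.065), Cldn1 at -1.50, Lcn2 at 1.55 and Sfrp2 at -2.45.

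At day 7, 149 genes changed in culture, 69 upwards and 80 downwards, and 119 by at least 2-fold. Among the falls, the tight junction gene Cldn11 fell by 6.35 (SE 0.87), the glypican Gpc3 fell by 3.82 (SE 0.60), Atp1b1, a sodium pump subunit, fell by 3.74 (SE 0.47), and the integrin Itga11, which binds collagen, fell by 3.14 (SE 0.48). Inmt, a methyltransferase, fell by 5.29, Itih2 fell by 3.95, Lancl3 fell by 3.43 and Sprr1a fell by 3.27, with limma adjusted p-values of 0.0059 to 0.037 over these 8 genes. Among the rises were the galanin receptor Galr2 (3.37, SE 0.40), the adhesion receptor Adgrg2 (2.61, SE 0.36) and the cannabinoid receptor Cnr1 (2.60, SE 0.38). Fndc1 (3.90), Pitpnm3 (2.85), Bricd5 (2.47), Hs3st6 (2.41) and the phosphodiesterase Pde2a (2.35) completed them, at adjusted p-values of 0.0059 to 0.038. Adipoq was at least 7.93-fold (adjusted p = 0.016), Lif at least 5.67-fold (0.0061) and Rnase12 at least 4.28-fold higher (0.041). The transglutaminase Tgm5 was at least 14.8-fold (0.032) and Myzap at least 6.53-fold lower (0.033). In all of these genes both treated arrays lay on the same side of both mock arrays. Of the 31 calls named for day 7, those of Foxc2 and Bricd5, 2 in all, passed in each of the 12 fits that left out 1 array. With the replicate number as a block 436 genes passed (195 up, 241 down), among them Pgk1 (adjusted p = 0.044), Mmp9 (0.031) and Tgfbi (0.046), while Fndc1 (0.057), Gpc3 (0.063) and Actg2 (0.063) did not. The total was 9 without day 7 mock replicate 2, 238 without day 7 mock replicate 1, and 12 and 19 without day 7 treated replicates 1 and 2. It was 96 without either treated glomerular array, 97 without either day 4 mock array and 81 without either day 4 treated array. Fitted on the 4 day 7 arrays alone, limma called 1 gene, and with normexp 57. With median scaling the calls split into 113 higher and 71 lower.

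At day 7, 2 lists passed, again 0 with an estimated correlation. Hypoxia and glycolysis genes were higher, 16 of 18 by their means, with a median of 0.52 (camera, adjusted p = 0.011; adjusted p = 0.95 with an estimated correlation), and 0 passed alone, with Pdk1 at 1.09. Oxidative phosphorylation genes were higher, 21 of 24 by their means, with a median of 0.15 (adjusted p = 0.023; adjusted p = 0.95 with an estimated correlation), and 0 passed alone. Both calls were lost without day 7 mock replicate 2 (adjusted p = 0.12 and 0.093) and without day 7 treated replicate 1 (0.11 each), and that of oxidative phosphorylation with quantile normalization (0.24). Limma's fry for movement one way called 0 lists, while its mixed form passed for several, among them slit diaphragm genes (adjusted p = 4.4e-06). Without day 7 mock replicate 1 the test called 6 lists and without day 7 treated replicate 2 it called 9. With the replicate block it called 6, adding slit diaphragm (adjusted p = 0.041), immune (0.00053) and interferon genes (0.00071), which were lower, and the unfolded protein response (0.044), which was higher.

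Podocyte members fell singly at day 7. Among slit diaphragm genes Inf2 fell by 0.94 (SE 0.11), Tjp1, the junction scaffold ZO-1, fell by 0.75 (SE 0.10) and Clic5, a foot process protein, fell by 1.57 (SE 0.24), at adjusted p-values of 0.017 to 0.033. The list had a median of -0.06 (adjusted p = 0.078), and 4 fell and 1 rose adjusted over the list alone. Among podocyte transcription factors Foxl1 rose by 1.69 (adjusted p = 0.021) and Foxd1 fell by 2.23 (SE 0.38, adjusted p = 0.045), 2 rose and 3 fell adjusted over the list alone, and the median was -0.41 (adjusted p = 0.25). The Foxl1 call was lost without day 7 mock replicate 2 (adjusted p = 0.11) or treated replicates 1 (0.12) and 2 (0.11), and that of Foxd1 whichever of the 12 arrays was left out (up to 0.27). Among surface and secreted genes Sema3e, a semaphorin, fell by 2.26 (SE 0.38, adjusted p = 0.045), a call lost in 11 of the 12 fits that left out 1 array. In that list 2 rose and 7 fell adjusted over the list alone, and the median was -0.06 (adjusted p = 0.34). Elsewhere Rgs5 fell by 2.82 (SE 0.30, adjusted p = 0.014), Cldn1, a claudin of parietal cells, fell by 1.95 (SE 0.29, adjusted p = 0.031) and Actg2 rose by 1.63 (SE 0.25, adjusted p = 0.032). The list medians were -0.01 for basement membrane (adjusted p = 0.56), 0.13 for actin (0.12), -0.06 for endothelial (0.84), -0.26 for mesangial (0.56), 0.14 for tubule (0.56), 0.18 for parietal (0.93), -0.75 for immune (0.078) and -0.11 for red blood cell genes, where the test pointed up (0.93). They were 0.26 for injury and matrix (0.56), -0.03 for cell cycle, with a mean of 0.01 and a test pointing up (0.93), 0.07 for p53 (0.31), 0.10 for cytokines (0.56), 0.28 for Notch (0.25), 0.32 for Wnt (0.26) and 0.09 for cholesterol synthesis (0.98). For estrogen response the median was 0.00 with a mean of -0.17 (0.84), for the unfolded protein response 0.16 (0.12), for immediate early genes -0.25 (0.1) and for interferon genes -0.29 (0.078), of which 19 of 19 were lower by their means. Lif was the 1 cytokine that passed. Adjusted over the list alone 3 basement membrane genes fell, 1 actin gene rose, 1 mesangial gene rose and 2 fell, 1 parietal gene rose and 2 fell, 2 cytokines rose and 2 fell, 2 Wnt genes rose and 1 fell, and 3 immediate early genes fell. Col18a1, a basement membrane collagen, was at -1.46 (adjusted p = 0.066), Tcf7 at 2.22 and Dusp1 at -1.70.

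**Figure D3:**
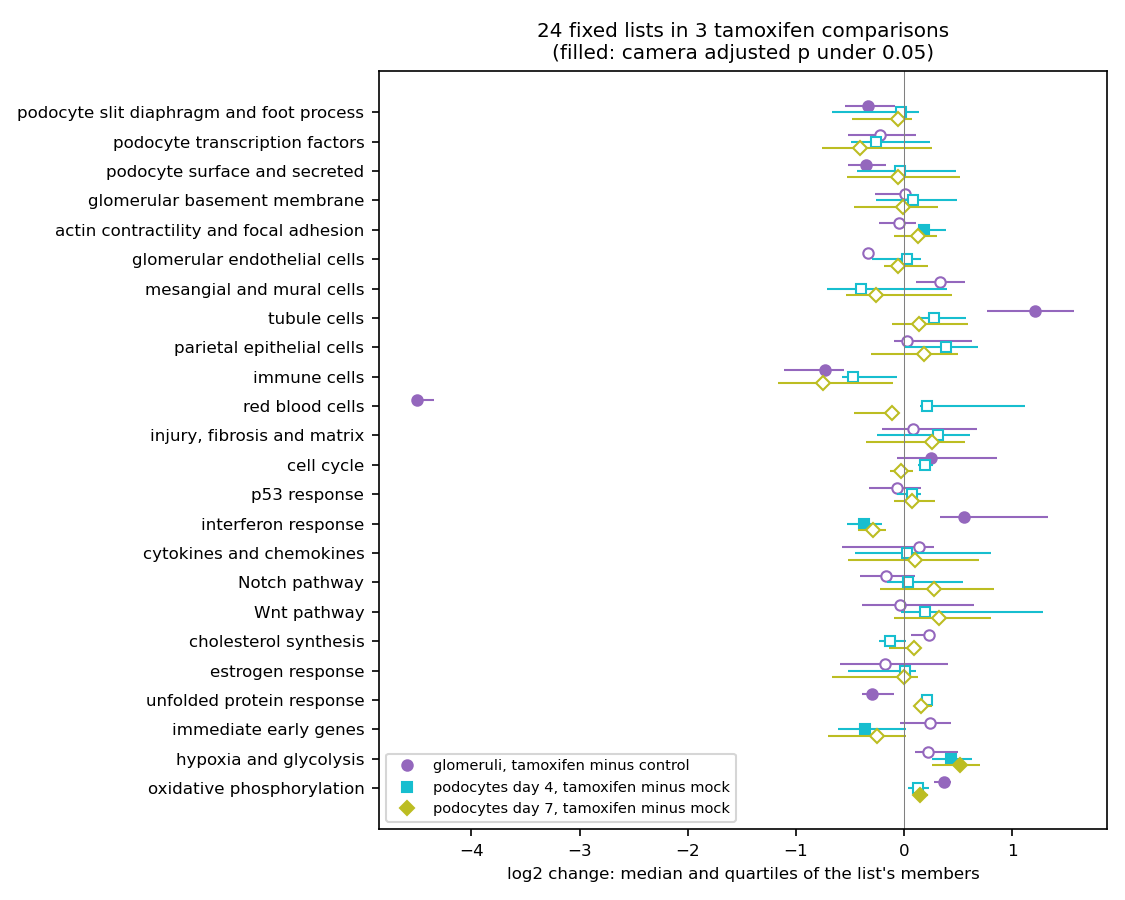
Median log2 change, with quartiles, of the members of 24 fixed lists (vertical axis) in glomeruli and in cultures at day 4 and day 7 (horizontal axis, treated minus untreated), filled where camera's adjusted p was under 0.05 with a preset correlation. Interferon genes have medians of 0.55 in glomeruli, -0.37 at day 4 and -0.29 at day 7, and hypoxia genes 0.43 and 0.52 in the cultures.

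Most genes called in culture at day 4 were called at day 7 too. Of the 32 genes called at day 4, 31 were also called at day 7 in the same direction, 13 up where independent lists would share 0.0635 and 18 down where they would share 0.0946 (Fisher's exact test, two-sided, p = 1.4e-30 and 1.2e-42), and 0 were called in opposite directions. Both days share 1 estimate of the spread and may share source cultures, since same-numbered mock samples of the days deviated together (correlation 0.55), so these p-values do not measure independent evidence. Of the 149 genes called at day 7, 145 had the same sign at day 4. The correlation of the changes across genes was 0.81, although genes are not independent replicates. A test of the difference between the day 7 and day 4 responses called 0 genes by limma at any setting that kept all arrays. In the fit on all 12 arrays without a block 136 genes had an unadjusted p under 0.05, and the smallest adjusted p was 1. It called 1 gene without day 4 mock replicate 2 and without either day 7 mock array. The differences ranked first by p did not pass: Atp2b3 at 1.93, Krt14 at 1.09, Sphkap at 1.04, Capn15 at 0.92, Pld6 at 0.95, Celsr3 at 0.86, Zfp983 at 0.57 and C2cd3 at 0.52 were above 0. Itpripl1 at -1.20, Anp32a at -1.09, Glp1r at -1.06, Cplx3 at -1.04, Ppfia4 at -0.96, Ctxn3 at -0.72, Ankmy1 at -0.66 and V1ra8 at -0.50 were below. With the replicate block 89 genes were shared by the days, and with the 4-array fits 0. The shared number was 17 without either treated glomerular array, 18 and 8 without day 4 mock replicates 1 and 2, 7 and 8 without day 4 treated replicates 1 and 2, 73 and 7 without day 7 mock replicates 1 and 2, and 9 and 12 without day 7 treated replicates 1 and 2.

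**Figure D4:**
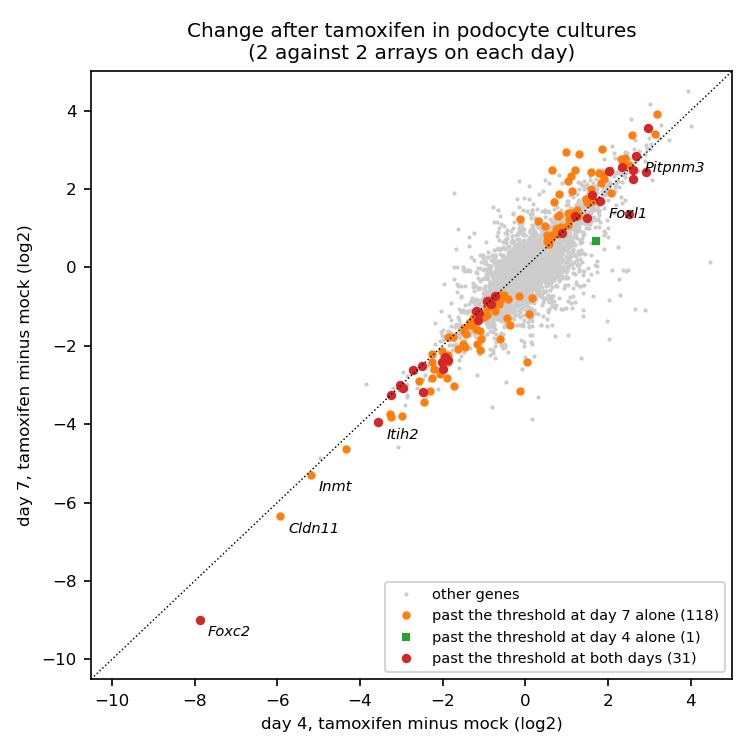
Log2 change after tamoxifen at day 7 (vertical axis) against day 4 (horizontal axis) for 15217 genes in podocyte cultures, with 2 against 2 arrays a day and colours for genes past an adjusted p of 0.05. The 31 genes past it on both days, Foxc2 lowest, lie near the dotted line of equal change.

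Glomeruli and day 7 cultures had 12 called genes in common and 0 in opposite directions, 7 up where independent lists would share 1.22 and 5 down where they would share 0.704 (Fisher's exact test, two-sided, p = 0.00021 and 7e-04). Both sets of calls use 1 estimate of the spread per gene, so genes of low spread can be called in both, and these p-values do not measure independent evidence. Beside Foxl1 and Foxc2, these were Ces1f (2.74 in glomeruli, 3.03 at day 7), C1ql3 (1.27 and 1.69), Tpd52l1 (1.12 and 0.82), Slc35g1 (0.87 and 0.92), the glycogen synthase gene Gys1 (0.70 and 0.74) and Rab11fip5 (0.59 and 0.67), all higher. The lower genes were Rhox3a (-1.47 and -0.78), Cabp5 (-1.11 and -0.94), Ddx25 (-0.96 and -0.69) and Lzts3 (-0.93 and -0.84). Day 4 cultures shared 2 calls with glomeruli, Foxl1 upwards, where independent lists would share 0.247 (exact p = 0.22), and Foxc2 downwards, where they would share 0.159 (exact p = 0.15). These 2 genes alone were called in all 3 comparisons. Across genes the glomerular change correlated at 0.18 with that at day 7 and at 0.17 with that at day 4, with genes again not independent replicates.

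The difference between the glomerular response and the mean of both culture responses passed for 166 genes, 94 of them higher in glomeruli relative to culture and 72 lower. Angptl7 was at 4.32 in glomeruli against a fitted -0.94 at day 4 and -1.30 at day 7 (fitted difference 5.44, SE 0.85, limma adjusted p = 0.037). It was well above background on 0 of 2 treated arrays at day 4 and 1 of 2 at day 7, and its bound at day 4 equals the fitted value. Adamts8 was at 3.49 against -0.31 and -0.42 (3.85, SE 0.44, adjusted p = 0.022). Atp1b1 was at 1.17 against -3.26 and -3.74 (4.67, adjusted p = 0.028) and Dpyd, which degrades pyrimidines, at 1.45 against -2.22 and -2.60 (3.86, adjusted p = 0.028). Foxc2 passed too (adjusted p = 0.022), but no treated culture read well above background, so its difference is only bounded, at 4.36 or more. Under normexp it did not pass (1.35, adjusted p = 0.33). In the other direction were Hbb-b2 (adjusted p = 0.028), Mmp8, the neutrophil collagenase (adjusted p = 0.048), Megf10 (2.56 and 2.62 in culture, adjusted p = 0.049), Wfdc21 (adjusted p = 0.04) and Galr2 (2.59 and 3.37 in culture, adjusted p = 0.045). Mmp8 did not read well above background in treated glomeruli, so its difference is bounded at -3.59 or below. For Hbb-b2 and Wfdc21 no culture read well above background, and for Megf10 and Galr2 no glomerular sample did, so the size of these 4 differences is not known. Of these 10 calls 0 passed in each of the 12 fits that left out 1 array. Among the lists, interferon (camera, median difference 1.07, adjusted p = 6.4e-07), tubule (0.84, 9.6e-06), oxidative phosphorylation (0.19, 8.7e-05), immediate early (0.67, 0.011) and mesangial genes (0.71, 0.029) were higher in the glomerular response, and red blood cell (-4.40, 2.5e-05) and unfolded protein response genes (-0.46, 0.0017) lower. With an estimated correlation the adjusted p = 0.61 for interferon, red blood cell and unfolded protein response genes, adjusted p = 0.36 for tubule, adjusted p = 0.81 for oxidative phosphorylation and mesangial and adjusted p = 0.74 for immediate early genes. With the replicate block 444 genes passed, but not Hbb-b2 (adjusted p = 0.059), Megf10 (0.064) or Galr2 (0.074). Under normexp the median of all genes was -0.14 in place of -0.05, and 4 genes passed. The total was 18 without control glomeruli replicate 1, 40 and 368 without treated glomeruli replicates 1 and 2, 21 and 11 without day 4 mock replicates 1 and 2, 6 and 7 without day 4 treated replicates 1 and 2, 41 without day 7 mock replicate 2, and 18 and 25 without day 7 treated replicates 1 and 2.

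Between mock cultures of day 4 and day 7 limma called 5 genes, 4 up and 1 down, against 988 at an unadjusted p under 0.05. The pheromone receptor gene V1ra8 was at least 2.03-fold, Mrgprb4 at least 2.98-fold and Glp1r, the receptor of an incretin hormone, at least 1.88-fold higher, 1700022A21Rik rose by 1.5, and 8430431K14Rik was at least 1.52-fold lower (adjusted p = 0.0093 for V1ra8 and 0.02 for the others). Genes next in p that did not pass were Xntrpc (1.38, adjusted p = 0.077), Krt73 (0.93), Dmrt1 (0.87) and Ddx25 (0.79) upwards, and Vezt (-1.06, adjusted p = 0.11), Kcnq1ot1 (-0.99), Gse1 (-0.81), Malat1 (-0.75), Dcaf12l2 (-0.62), Psme4 (-0.52) and Utrn (-0.49) downwards. The 2 times lay on separate slides, so time and slide cannot be told apart here. With the replicate block, with normexp and in the 4-array fit limma called 0. It called 2 without either control glomerular array, 1 without either treated glomerular array or day 4 mock replicate 2, and 0 without either day 4 treated or either day 7 mock array.

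Untreated cultures differed from control glomeruli in most genes: 9697 passed, 5755 higher in culture and 3942 lower, and 5020 by at least 2-fold (2491 higher, 2529 lower). Smoc2, a matrix protein, was higher by 11.05 (SE 0.58, limma adjusted p = 2.4e-06), the actin-binding calponin Cnn1 by 8.96, Ltbp2 by 8.50 and Itga11 by 7.61. Among genes measured in both, the largest differences the other way were those of Miox, a proximal tubule enzyme, at -10.73 (SE 0.28, adjusted p = 6.9e-08), Fxyd2 at -10.00, and the endothelial claudin Cldn5 at -9.93, besides the muscle gene Myom2 at -10.82 (SE 0.45, adjusted p = 7.6e-07) and Sfrp2 at -9.84. These calls passed in each of the 12 fits that left out 1 array. Podocyte genes chosen after their values were seen were lower in culture to different degrees: Nphs1, which encodes nephrin, at -4.33, Podxl at -4.19, Synpo at -0.80 and Wt1 at -0.67. Umod, of the thick ascending limb, was well above background in 0 of the 4 mock cultures, but the tubule gene Slc34a1 was in 2 and Lrp2 in 4. The endothelial genes Pecam1, Kdr and Cdh5 and the immune gene Ptprc were also well above background in 4, though all were lower than in glomeruli. Chosen in the same way, Acta2 was higher in culture at 6.16, Tagln at 4.85, Col1a1 at 7.47 and the proliferation marker Mki67 at 3.8. Each kind of sample lay on its own slide, so kind of sample and slide cannot be told apart. With each array scaled to its median the calls split into 7191 higher and 3026 lower, and the median of all genes was 0.41 in place of 0.178, so that list medians close to 0 have no settled sign.

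The fixed lists described that contrast further, counted here as members that rose or fell in culture. Of podocyte slit diaphragm genes 6 rose and 17 fell of 26 (median -1.32), of podocyte transcription factors 3 rose and 7 fell of 15 (-0.47), of surface and secreted genes 6 rose and 17 fell of 31 (-1.09), and of basement membrane genes 7 rose and 7 fell of 16 (0.21). Of endothelial genes 22 of 22 fell (-6.17), of mesangial genes 15 of 17 (-2.16), of tubule genes 23 of 24 (-6.84) and of red blood cell genes 4 of 5 (-9.27), with 0 rising in each. Immune genes had 4 rises and 7 falls of 20 (-0.09), and parietal genes 6 rises and 4 falls of 11 (2.59). Actin and focal adhesion genes had 20 rises and 1 fall of 25 (1.79), injury and matrix genes 18 and 4 of 29 (1.99), cell cycle genes 18 and 3 of 26 (2.59), p53 genes 13 and 2 of 20 (1.77), and hypoxia genes 13 and 2 of 18 (1.16). Interferon genes had 0 rises and 8 falls of 19 (-1.41), Notch 2 and 11 of 15 (-2.04), Wnt 3 and 8 of 17 (-0.81) and cytokines 9 and 4 of 17 (1.02). Cholesterol synthesis had 9 and 2 of 24 (0.47), estrogen response 6 and 2 of 9 (1.93), the unfolded protein response 5 and 0 of 19 (0.09), immediate early genes 5 and 5 of 16 (0.48) and oxidative phosphorylation 4 and 6 of 24 (-0.02).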

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

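The contrast between the glomerular and culture responses was set in advance. Chosen only after their results were seen were the tests of the mesangial against the endothelial list, of tubule genes in culture, and of Foxl1, its neighbours and the estrogen list, while the second marker lists were written before their values were known.

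The response to tamoxifen differed between glomeruli and cultures for 166 genes by a test of the difference itself. The fitted differences (glomeruli minus the mean of both culture days, log2) were 4.67 for Atp1b1, 3.86 for Dpyd and 3.85 for Adamts8. That of Angptl7 was 5.44 (SE 0.85), with treated cultures dim at day 4 and a bound equal to this fitted value. That of Foxc2 was 5.61 and that of Mmp8 -4.65, but with treated cultures (Foxc2) or treated glomeruli (Mmp8) not well above background only 4.36 or more and -3.59 or below can be read on this scale, and with normexp Foxc2 was at 1.35 and Mmp8 at -1.60. Fitted at -5.55 for Hbb-b2, -3.88 for Megf10, -3.62 for Wfdc21 and -2.86 for Galr2, the others have no known size, as all cultures (Hbb-b2, Wfdc21) or all glomeruli (Megf10, Galr2) were dim. Among 6409 probes without a gene name, used in no comparison above, 62 passed in glomeruli (24 up, 38 down), 1 at day 4 and 6 at day 7.

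Tubule genes were higher in treated glomeruli. A second list of proximal tubule genes, none of them in the fixed lists, had a median of 1.61 over 19 genes, all 19 measured in both control samples, 18 higher on both treated arrays and 6 past the threshold. Its 3 members with the brightest probes in controls, which do not rank abundance between genes, went from 4.64 to 4.42 (Cyp4b1), 3.57 to 5.02 (Slc27a2) and 3.11 to 4.81 (Pdzk1). All segments alike is argued against, since distal and collecting duct genes lay lower by a difference of -0.84 (median 0.77). An equal dilution of every glomerular cell type would lower all their lists, and the mesangial median lay 0.66 above the endothelial one. This does not decide it. By camera neither list passed at the main setting (adjusted p = 0.055 each) or with an estimated correlation (0.81 each), and the mesangial list also holds mural genes. A larger carry-over of proximal tubule is a candidate source. A rise in the tubules after gene loss was not tested. One in the podocytes themselves stays open, because only 6 tubule genes were measured on all 8 culture arrays (median 0.12).

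Red and white blood cell genes were lower in treated glomeruli. Less blood of every kind would lower all classes. In a second red cell list only 1 gene, Hemgn, was measured in both controls, and it was at 0.46 (SE 0.2). Among classes with at least 3 measured genes the highest median was 0.27, that of 6 platelet genes. These were dim in controls (-4.79 to -2.14, where the lowest signal well above background was -5.80) but measured there. Of them 0 were higher and 1 was lower on both treated arrays, and Treml1, at 0.20, had an SE of 1.67. Their median is too imprecise to decide, so less blood stays open. Loss of red cells alone is argued against by the neutrophil median of -2.0 and the lymphocyte median of -0.88. The latter was the second highest of the white cell and platelet medians. Among neutrophil genes S100a9 went from 3.87 in control to 1.58 in treated glomeruli, but Csf3r, the brightest in controls, only from 4.75 to 4.37. Fewer resident immune cells may contribute, as resident macrophage genes had a median of -0.52, but this carries little weight: of only 4 genes Folr2 (-5.76 in controls, change 1.02) and Lyve1 (-5.43, change -0.58) lay near the lowest readable signal, which leaves Mertk (3.10 to 2.44) and Stab1 (2.49 to 2.02). Mouse to mouse differences and an effect of gene loss stay open, untested.

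Foxl1 was higher in all 3 comparisons in which Foxc2 was lower. The shift of tubule and red blood cells seen in glomeruli is argued against as the whole cause by its rise of 1.69 at day 7 in culture. There the tubule median was 0.14 and the red blood cell median -0.11. Only 6 of 24 tubule and 1 of 5 red blood cell genes were well above background on all culture arrays. These medians thus rest in part on dim genes. A change of other cells within the cultures stays open, as Rgs5 fell by 2.82 at day 7 and the immune list had a median of -0.75 there. A general opening around the deleted genes stays open: the highest change among measured neighbours in culture was 1.05, for Foxq1 at day 4 (adjusted p = 0.51, limma), which read well above background on 1 of 8 culture arrays, while Mthfsd was at 0.38 and 0.27 and Gmds at 0.56 and 0.45. Tamoxifen itself and the loss of the genes cannot be told apart without treated samples that keep both genes, although the estrogen response list did not pass in culture (smallest adjusted p = 0.54).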

How the results depend on the processing

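All alternatives except the block shared by the culture groups were planned, and the cause was not tested where a result moved unless stated. Every gene called at the main setting in glomeruli (402), at day 4 (32) and at day 7 (149) kept its sign under quantile or median scaling, the authors' value table and probe averaging. The blocks, the other variance prior and the smaller fits leave each change as it is, so they test only its p-value. Under normexp 391, 28 and 148 did, and 148 at day 7 without the filter. The filter on all 4 arrays of a comparison tested only 370, 23 and 118 of them.

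Normexp gave 5 genes in glomeruli, 5053 at day 4, 57 at day 7, 4 for the glomerular against culture difference, 0 for mock day 7 against day 4 and 55 shared by both days, with 5 lists at day 7. It turned the actin list at day 4 downwards (-1 for its direction, adjusted p = 0.13) and put Shisa3 at 0.14, Hspa12a at 0.48, Adamts18 at 0.34 and Ctxn3 at 1.02 at day 4. Quantile normalization gave 52 genes at day 4, 3 for mock day 7 against day 4 and 49 shared, with 2 lists at day 4 and 1 at day 7, and median scaling 4 lists at day 7. Without the filter there were 258 genes in glomeruli, 107 for the difference and 10 between mock days. With the filter on all 4 arrays there were 15 at day 4 and 14 shared. Trend and robust options gave 82 at day 4, 0 between mock days and 76 shared.

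With the replicate block there were 90 genes at day 4, 436 at day 7, 444 for the difference, 0 between mock days and 89 shared, and 6 lists at day 7. In glomeruli, where the samples share only a number, the block moved 402 to 460 and kept 207 of the calls. There it also brought in the endothelial (camera, adjusted p = 0.027), mesangial (0.037), cholesterol synthesis (0.0043) and hypoxia lists (0.017). Of the named culture results it changed no call other than those given with them. The shared culture block gave 269, 500, 443, 1 and 235 in the same order. Own-array fits, which have 2 residual degrees of freedom, gave 0 in glomeruli, 0 at day 4, 1 at day 7, 0 between mock days and 0 shared. Separate fits of glomeruli and cultures gave 0, 18, 39, 0 and 15. A 2-fold minimum left 261 genes in glomeruli and 5020 between cultures and glomeruli. An estimated correlation called 0 lists in each comparison, and fry for movement one way 3 in glomeruli and 0 at either day. The difference between the culture days stayed at 0 genes under every setting with all arrays. The slide as a block was not run, since each contrast within a slide leaves it without effect and the others are confounded with it.

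Leaving out 1 array at a time, where the lone array left is assumed to vary like the other groups, gave 89 to 495 genes in glomeruli, 7 to 79 at day 4, 9 to 238 at day 7, 0 to 1 between culture responses, 6 to 368 for the glomerular against culture difference, 0 to 7 between mock days, 8245 to 9588 between cultures and glomeruli and 7 to 73 shared, with 7 to 11 lists in glomeruli, 2 to 6 at day 4 and 2 to 9 at day 7. Over single genes and lists in all settings, 4872 gene values and 1525 list values counted as the same, 826 and 57 lost a call, and 64 and 76 gained one. Another 25 and 66 moved without a call, and 4 and 1 that were called reversed their direction, all under normexp. An uncalled gene whose sign changed by less than 1 SE counted as the same, and several settings leave each change as it is. For genes near background, signal over background limits what can be read. Where a group was dim throughout, a size can at most be bounded, and fitted values printed for such genes are not settled sizes.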

Other observations

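The marker lists described here were written before their values were known, and their members named here were picked after they were seen.

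Neutrophil and lymphocyte genes outside the fixed lists were lower in treated glomeruli. Of 6 neutrophil genes, 6 were lower on both treated arrays, and Cxcr2, the chemokine receptor of neutrophils, fell by 1.36 (adjusted p = 0.022, limma). Its treated mean of -5.22 lay near the lowest signal well above background (-5.8), so the size of that fall is not settled. S100a8 was at -2.74 and Retnlg at -2.02 without passing. Of 8 lymphocyte genes 8 were lower by their means and 6 on both treated arrays, with Cd79b, part of the B cell receptor, at -1.56 (adjusted p = 0.072). Among proximal tubule genes outside the fixed lists Hao2 rose by 1.94 (adjusted p = 0.015), Slc6a19 rose by 1.84 (0.049), Pdzk1 rose by 1.70 (0.045), Acsm2 rose by 1.68 (0.032), Ggt1 rose by 1.54 (0.023) and Cyp2j5 rose by 1.45 (0.034), and of the distal genes Scnn1a, a subunit of the epithelial sodium channel, rose by 0.90 (0.027) and Kcnj1 rose by 0.77 (0.033). Of a second red cell list only Hemgn was measured in both controls, and it was at 0.46 (adjusted p = 0.27), unlike the haemoglobin genes.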
